A study of Rattus norvegicus with 24 samples.

How the data were processed

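Heart muscle RNA of 24 rats was measured on single-colour Agilent gene expression arrays, with 4 rats in each of 6 groups and 2 males and 2 females per group, per the labels. The groups were a sham group, a group with myocardial ischaemia-reperfusion injury (IRI) made by tying off the left anterior descending coronary artery, and 4 groups with the same injury after 7 days of acupuncture at the Jiaji, Neiguan, Yanglingquan or Quchi acupoint. Total RNA was isolated with TRIzol and labelled with Cy3, per the labels' protocols. The times of reperfusion and of tissue collection are not given in the sources used here. Each array was taken as 1 animal, as the labels number the samples within groups; p-values measure the spread between these samples.

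The scanner files hold spot intensity values, which Agilent Feature Extraction 11.0.1.1 had background-subtracted and spatially detrended within each array, per the file headers; the submitters' processing notes name version 10.7.3.1. A table of log2 values deposited by the authors for the same arrays was used as an alternative. Its columns share a median of 7.20 and equal quartiles, and they followed the log2 processed intensity of the matching array closely, so these deposited values were taken as quantile normalized log2 signals with no gene centring; the tool that normalized them is not given in the sources used here. The spot flags (other values, 0 or 1) were set by Feature Extraction, per the file headers.

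Of each array's spots, 1377 were controls and were left out, and 42877 were kept. Over all arrays 8733 spots marked as non-uniform or population outliers were left out, and 0 spots were saturated. Spots of a probe were averaged, which left 30367 probes. Accessions of the array files were matched without version to the transcripts of a rat RefSeq gene table, which gave the gene symbols. This named 18005 probes (59.3%) for 15168 genes. The other 12362 probes stayed unnamed here. A probe passed the filter when it was well above background on all arrays of at least 1 group, and 25149 probes did. A gene was represented by its passing probe of highest mean signal, which gave 12894 genes for testing, of which 10879 were well above background on all arrays. Where another probe of a gene named as called in a comparison went the other way there, its value is given.

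The main values were log2 of the processed signal minus the 75th percentile of each array, so a level of 0 marks the array's 75th percentile. Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) over all 24 arrays, with group and sex in the model, 17 residual degrees of freedom, Benjamini-Hochberg adjustment over the 12894 genes and a threshold of adjusted p of 0.05. Genes past it are referred to as called. The same fit gave IRI against sham, each acupoint group against IRI and against sham, a moderated F test among the acupoint groups, and females against males. The interaction of injury and sex came from a fit of 12 group-by-sex means. All p-values are two-sided, and fold changes are on the log2 scale with their standard errors (SE). Where a gene was well above background on 0 arrays of 1 group, only a bound is given: the mean of the brighter group against, per array of the dim group, the higher of the lowest well-measured signal and the probe's own value.

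Gene lists numbering 31, with 604 genes of which 551 were tested, were fixed before the data were examined and compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 31 lists. Camera was run again with the correlation estimated from the residuals. A reversal score measured whether an acupoint group lay on the sham side of IRI. The 4 IRI arrays were split into 2 and 2, 500 genes were chosen and signed by their difference between sham and the first 2, and the signed mean difference of the acupoint group from the other 2 was averaged over all splits. Its p came from an exact permutation test over 70 assignments of 8 arrays, adjusted over the 4 acupoints. Correlations of fold changes between acupoint groups were set beside simulated unchanged groups sharing the same IRI arrays. The genes to be named were chosen by a rule fixed before the data were examined: per comparison the 10 higher and 10 lower called genes of largest fold change with no overlap between the groups' arrays, up to 3 genes of smallest p per list that passed or had at least 3 called members, the 10 genes of smallest p in the F test, and a fixed panel of injury, stress, metabolic, clock and sex-linked genes. Hspa1b, Ddx3y and Xist of that panel had no named probe here.

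Some details were settled only once the values were at hand. Only named genes entered the main tests, with every probe as an alternative. The normexp alternative used the median spot signal, with an offset of 50, in place of the planned mean signal. For camera, the reversal score and principal components, missing values (231 genes) were filled with the group mean. The lists of liver transcripts, of the clock's evening and morning arms and of receptor genes, the brightness-matched lists and the comparison of each acupoint with the others were chosen after seeing the data. Alternatives set before the data were examined were quantile normalization, median scaling, normexp, the authors' deposited values, no filter, a stricter filter, every probe, no sex term, replicate number as a block, scan as a random block, only the compared groups, array weights, a trended robust prior, a 2-fold threshold, and leaving out each array in turn. Counts under several scalings had been looked at before the final fits were written; the main setting is the one fixed beforehand. The 2-fold bound of the pattern shared by all acupoint groups followed a look at a 4-fold bound. A probe counted as well above background where most of its spots were. Array outliers were sought with Dixon's test in 6 array measures and the fixed panel.

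The fits were tested on simulated data with 12663 genes, each drawn independently, with no correlation between genes and no difference between slides. For IRI against sham, limma recovered 76 of 100 genes changed by 1 and 93 of 100 changed by 2 on the log2 scale, and 7.14% of its calls were unchanged genes. For the comparison among acupoints, the F test recovered 191 of 200 genes changed by 2. For Yanglingquan against IRI, camera found the list raised by 0.5 and 0 others, a setting that does not test the preset correlation on correlated genes. With the injury changes taken back in Jiaji and kept in Neiguan, the reversal scores were -0.63 (exact permutation p = 0.0143, the smallest the test can give) and -0.01.

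Slide and scan were read from the file headers. The arrays came from 7 scans on 3 days, with sham and IRI on the first day, 15 acupoint arrays on the second and Quchi replicate 1 on the third. Each of the other groups lay in 1 scan of its own, so group and scan cannot be told apart except for the 2 scans of Quchi, and acupoint groups and scan day cannot be told apart either. With 4 arrays per group, their number limits the precision.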

Results

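The series asked how acupuncture pretreatment acts before myocardial ischaemia-reperfusion injury, with sham rats, injured rats and injured rats pretreated at 1 of 4 acupoints: Jiaji beside the spine, Neiguan on the forearm, Yanglingquan on the leg and Quchi at the elbow. Myocardial RNA of 24 rats was measured, 4 per group. The share of probes well above background was 73.5 ± 2.51% (SD, n = 4) in Yanglingquan and between 80.1% and 84.8% on average in the other groups. Arrays of a group correlated at r = 0.976 to 0.993 across genes and arrays of different groups at 0.964 to 0.991, and 23 of 24 arrays had an array of their own group as the closest. Eif2s3, an X-linked translation factor gene that escapes inactivation, lay between 2.78 and 3.23 in the 12 females and between 2.07 and 2.43 in the 12 males on the log2 scale, so every array matched its sex label. Every group was hybridised on slides of its own, and the acupoint arrays were scanned on other days than sham and IRI.

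**Figure D1:**
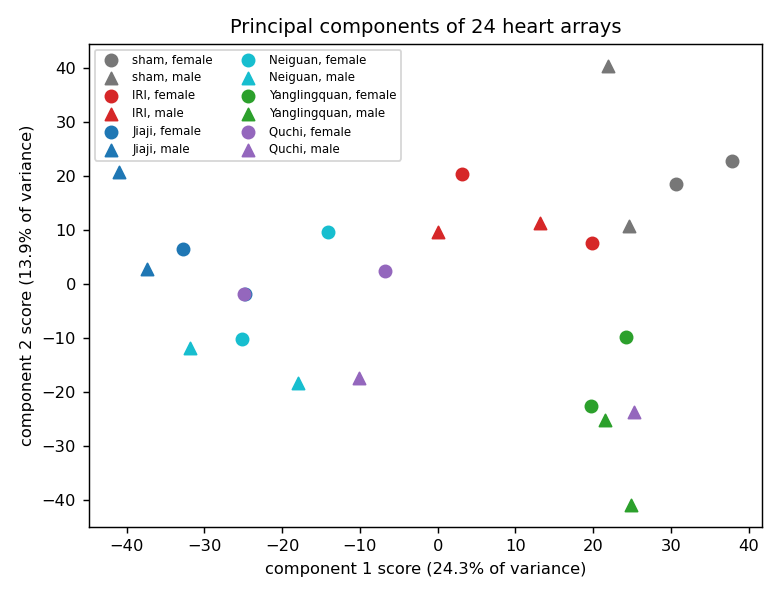
Scores of the 24 arrays on the first 2 principal components of 12894 genes (axes: component scores with percent of variance, 24.3% and 13.9%); colours are groups, circles females and triangles males. The sham arrays lie at the right end of component 1 above the Yanglingquan arrays, and the Jiaji and Neiguan arrays lie on its left side.

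Some genes of the early inflammatory and immediate early response were called higher in IRI than in sham, whose arrays lay on separate slides. Cxcl1, a chemokine that draws neutrophils, was higher in IRI than in sham by 2.05 ± 0.38 (SE) on the log2 scale (limma adjusted p = 0.00223), from 0.82 ± 0.62 (SD, n = 4) to 2.87 ± 0.71. The cytokine gene Il6 rose by 2.14 ± 0.54 (adjusted p = 0.0213), the inducible nitric oxide synthase gene Nos2 by 0.82 ± 0.18 (adjusted p = 0.00772), and Cxcr2, the neutrophil receptor for Cxcl1, by 1.05 ± 0.27 (adjusted p = 0.0215). Of the immediate early transcription factors, Fosl1 rose by 2.21 ± 0.49, Myc by 1.22 ± 0.24 and Egr3 by 0.82 ± 0.22 (adjusted p = 0.00901, 0.00338 and 0.0288). Another Egr3 probe stood at 0.11. The calls of Il6, Cxcr2 and Egr3 each ended when any of several single arrays was left out, Il6 without IRI replicate 2 or 4 or sham replicate 2 or 3 (adjusted p = 0.057 to 0.0849). With normexp the calls of Il6, Cxcr2, Egr3 and Fosl1 ended (1.47, 0.38, 0.14 and 0.67).

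By list, 3 of 26 immediate early genes, 5 of 26 genes of inflammatory cytokines and adhesion and 1 of 15 neutrophil markers were called higher, 0 lower, and 6, 5 and 4 when adjusted over the list alone. The 3 lists lay above other genes by camera, with median log2 fold changes of 0.31, 0.37 and 0.69 (adjusted p = 0.00266, 0.003 and 0.0041), and these calls did not hold with an estimated correlation (adjusted p = 0.962 for each with an estimated correlation). The neutrophil genes Fpr1 and Elane differed by 0.82 ± 0.24 and 1.53 ± 0.49 without passing (adjusted p = 0.051 and 0.0763), as did the stress factor gene Atf3 at 1.13 ± 0.35 (adjusted p = 0.0624). The calprotectin genes S100a8 and S100a9 stood at 1.002 ± 0.57 and 1.22 ± 0.52 (adjusted p = 0.393 and 0.215). Of wall stress and fetal genes, 2 of 13 were called higher, namely Cdkn1a at 0.60 ± 0.13 and Tnfrsf12a at 0.78 ± 0.21 (adjusted p = 0.0103 and 0.0331, named after their values were seen), and the list did not pass (median 0.24, adjusted p = 0.106, 0.962 with an estimated correlation). For its members Nppa, Nppb and Ankrd1 the values were 0.34 ± 0.63, 0.10 ± 0.24 and -0.03 ± 0.24, and for the myosin heavy chains Myh6 and Myh7 0.08 ± 0.15 and 0.04 ± 0.14, none past the threshold (adjusted p = 0.863 to 0.974).

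In all, 743 of 12894 genes were called between IRI and sham, 610 higher and 133 lower in IRI. The largest increases included Stfa3l1, a stefin A family gene, at 2.75 ± 0.56 (adjusted p = 0.00489), and several faint genes of olfactory receptors. Or7g23e was at least 4.35-fold and Or8j3 at least 2.18-fold higher, being well above background on 0 sham arrays. The largest decreases were Clic6, a chloride channel family gene, at -3.33 ± 0.83, and Cntn4, a neuronal adhesion gene, at -1.99 ± 0.33 (adjusted p = 0.0204 and 0.000955); Clic6 was no longer called without IRI replicate 2 (-2.13) or without sham replicate 1 (-3.13). Esr2, oestrogen receptor beta, was lower by -2.15 ± 0.33 at its chosen probe (adjusted p = 0.000584), while its other 2 probes averaged 0.07. Genes of smell, pheromone and taste receptors made up 130 of the calls, 110 of them higher, out of 576 tested. Without sham replicate 3 the count was 440. Quantile normalization gave 550 higher and 267 lower, median scaling 506 and 254, and the authors' processed values 544 and 273.

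**Figure D2:**
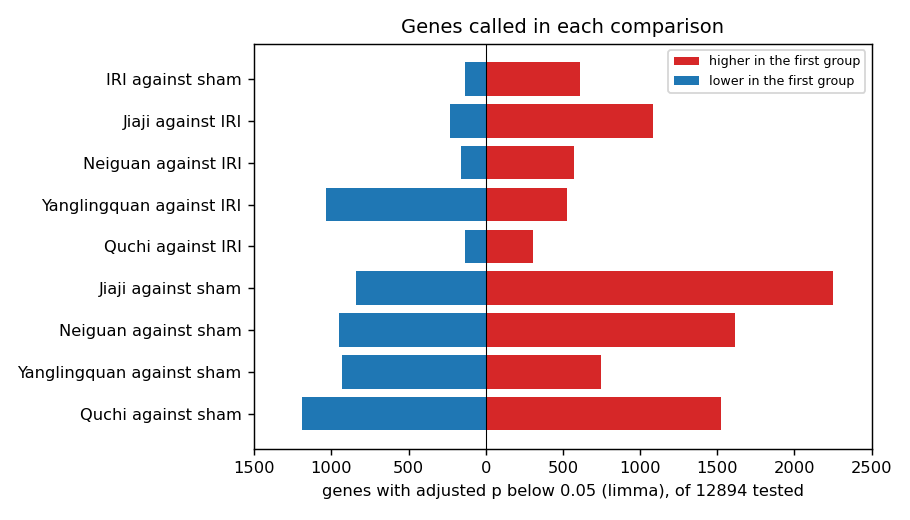
Numbers of genes called by limma (horizontal axis, of 12894 tested) in each comparison; red bars to the right count genes higher in the first group and blue bars to the left genes lower. Lower genes outnumber higher genes in Yanglingquan against IRI (1036 and 527) and in Yanglingquan against sham (931 and 749).

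Against IRI, several single genes of red cells were called lower in Jiaji, while the list that holds red cell markers did not pass (adjusted p = 0.105). The haemoglobin beta genes Hbb-bs, Hbb-b1 and Hbb fell by 1.47 ± 0.34, 0.88 ± 0.23 and 0.56 ± 0.17 (adjusted p = 0.00748, 0.0172 and 0.0417), and Alas2, which starts haem synthesis in red cell precursors, by 1.09 ± 0.27 (adjusted p = 0.0119). The epsilon globin gene Hbe2 was lower by 1.16 ± 0.24 (log2 fold change -1.16, adjusted p = 0.00321). Other probes of Hbb-b1 and Hbb stood at -1.07 and -1.51. The mast cell protease gene Mcpt1 fell by 1.41 ± 0.34 and the neurotrophin receptor gene Ntrk2 by 1.17 ± 0.20 (adjusted p = 0.0108 and 0.000668). Higher genes included Slc6a2, the noradrenaline transporter, at 0.84 ± 0.11, Adrb1, the main cardiac beta adrenoceptor, at 0.54 ± 0.14, and Pde4d, which breaks down cyclic AMP, at 0.77 ± 0.20 (adjusted p = 3.07e-05, 0.0139 and 0.0139); another Pde4d probe stood at 0.15. Nos2, the cytokine brake gene Socs3 and the anti-inflammatory cytokine gene Il10 were higher by 1.01 ± 0.18, 0.76 ± 0.16 and 0.78 ± 0.19 (adjusted p = 0.000688, 0.00414 and 0.0113), and the clock gene Per1 by 0.50 ± 0.14 (adjusted p = 0.023). With quantile normalization Adrb1, Il10 and Per1 stood at 0.30, 0.57 and 0.27 and were no longer called (adjusted p = 0.121, 0.0686 and 0.156), and the calls of Hbb-b1, Hbb and Alas2 ended without the sex term or without single arrays such as Jiaji replicate 3 (adjusted p = 0.0801, 0.159 and 0.0515).

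Of the 31 lists, 0 passed for Jiaji against IRI. Erythrocyte and platelet markers came closest with cell cycle genes (4 of 12 and 1 of 19 called lower, adjusted p = 0.105 for both, and 0.954 with an estimated correlation); adjusted over the list alone 5 erythrocyte and platelet markers were called lower. Of adrenergic and cholinergic signalling, 3 of 22 genes were called higher (list adjusted p = 0.505). Of glycolysis and hypoxia response, the carbonic anhydrase gene Car9 was higher by 0.48 ± 0.12, and the glycolytic genes Eno1 and Pfkp fell by 0.49 ± 0.13 and 0.59 ± 0.17 (adjusted p = 0.0104, 0.0223 and 0.0331); Car9 and Eno1 were not called with quantile normalization (adjusted p = 0.0638 and 0.0654), nor Pfkp without any of several single arrays. Cxcl2, Il1b and Atf3 differed from IRI by -0.91 ± 0.52, -0.57 ± 0.35 and -0.32 ± 0.35 without passing (adjusted p = 0.306, 0.356 and 0.64).

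The count of called genes was 1314 for Jiaji, 1082 higher and 232 lower. It was 861 without IRI replicate 2. The split moved with the scaling: 742 higher and 635 lower with quantile normalization, 741 and 1630 with median scaling, 761 and 351 with normexp, and 750 and 630 with the authors' processed values. Median scaling moved the median of all genes in this comparison to -0.23 from -0.01 in the main values.

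In Neiguan the lists of inflammatory and interferon genes passed upward with the preset correlation only, and single clock genes were called. Inflammatory cytokines and adhesion lay above other genes, with a median of 0.38 and 3 of 26 called higher (camera adjusted p = 0.0015, and 0.956 with an estimated correlation). These were Nos2 at 1.12 ± 0.18, Socs3 at 0.72 ± 0.16 and Il10 at 0.74 ± 0.19 (adjusted p = 0.000415, 0.00877 and 0.0256). The interferon response list had a median of 0.54 with 0 of 24 genes called (camera adjusted p = 0.00166, 0.956 with an estimated correlation, and 0.259 without IRI replicate 4). Its genes included the chemokine gene Cxcl10 at 1.60 ± 0.64 and the GTPase gene Gbp2 at 0.94 ± 0.39 (adjusted p = 0.166 and 0.181). Bmal1, a core activator of the circadian clock, fell by 1.501 ± 0.37 (adjusted p = 0.0183) from 0.33 in IRI to -1.17 in Neiguan, and its other probe stood at -1.42. The clock repressor gene Per3 was higher by 1.16 ± 0.15 (adjusted p = 5.35e-05), while its other 2 probes averaged 0.30. Npas2, a partner of the clock activators, stood at -1.11 ± 0.27 at its chosen probe (adjusted p = 0.0139) and at 0.48 at its other probe. The Bmal1 call ended without IRI replicate 1 or 2 or Neiguan replicate 4 (adjusted p = 0.0547, 0.0698 and 0.0722), and the circadian clock list as a whole did not pass (1 of 15 higher, 2 lower, adjusted p = 0.492).

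Among faint genes, Hmga2, a chromatin protein gene of growing cells, was at least 1.53-fold lower in Neiguan, and P2rx7, an ATP-gated channel gene of immune cells, at least 1.38-fold lower. Monocyte and macrophage markers lay just outside the threshold (median 0.35, adjusted p = 0.0509). Il6, Ccl2, S100a8 and Timp1 differed from IRI by 0.38 ± 0.54, 0.44 ± 0.44, 0.12 ± 0.57 and 0.50 ± 0.22 (adjusted p = 0.217 to 0.931). Of all genes, 727 were called, 569 higher and 158 lower. The count was 461 without IRI replicate 2, 456 without Neiguan replicate 1 and 476 without Neiguan replicate 4; quantile normalization gave 562 higher and 318 lower, median scaling 494 and 317, and the authors' processed values 563 and 306.

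Scaled to the 75th percentile, Yanglingquan showed higher genes of heart muscle and energy metabolism and lower genes at the faint end of the arrays. Of fatty acid oxidation, 7 of 27 genes were called higher and 0 lower (10 when adjusted over the list alone; median 0.53, camera adjusted p = 9.15e-08, 0.417 with an estimated correlation). Acadl, which opens beta oxidation of long chains, was higher by 0.70 ± 0.13, the fatty acid transporter gene Cd36 by 0.76 ± 0.16, Etfb, an electron carrier, by 0.58 ± 0.13, and Cpt1b, which admits fatty acids to mitochondria, by 0.56 ± 0.14 (adjusted p = 0.00199, 0.00445, 0.00726 and 0.0129). Of oxidative phosphorylation, 16 of 34 genes were called higher (25 over the list alone, median 0.35, adjusted p = 1.35e-14, 0.417 with an estimated correlation), among them Atp5f1a of ATP synthase at 0.61 ± 0.11 and Uqcrb of complex III at 0.67 ± 0.13 (adjusted p = 0.000937 and 0.0016). Another probe stood at 0.06 for Uqcrb, 0.44 for Cd36 and 0.34 for Cpt1b. Of cardiomyocyte markers, 10 of 18 were called higher (10 over the list alone; median 0.49, adjusted p = 4.31e-07, 0.417 with an estimated correlation), with the light chain gene Myl3 at 0.80 ± 0.13, troponin I (Tnni3) at 0.68 ± 0.12, Myh7 at 0.68 ± 0.14 and Myh6 at 0.56 ± 0.15 (adjusted p = 0.000412, 0.000937, 0.00367 and 0.0186).

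Those 2 lists are made of bright genes, and their direction depended on the scaling. Random lists of equal brightness had medians of 0.39 and 0.41, so oxidative phosphorylation stood at the 18.8 percentile of such lists and cardiomyocyte markers at 89.8, whereas fatty acid oxidation stood at 100. With quantile normalization both lists lay below other genes without passing (adjusted p = 0.487 and 0.56), as they did with normexp and the authors' processed values, while fatty acid oxidation passed upward with each of these. Of single genes named for these 3 lists, none stayed called with quantile normalization: Acadl, Cd36, Etfb and Cpt1b stood at 0.12, 0.39, 0.14 and 0.12, Atp5f1a and Uqcrb at 0.04 and 0.07, and Myl3, Tnni3, Myh7 and Myh6 at 0.17, 0.02, 0.11 and -0.13. The chaperone genes Cryab and Hspa8 were higher by 0.78 ± 0.14 and 0.69 ± 0.14 (adjusted p = 0.00142 and 0.0032), and the autophagy genes Map1lc3a and Map1lc3b by 0.68 ± 0.15 and 0.45 ± 0.11 (adjusted p = 0.00503 and 0.0116), and these calls too ended with quantile normalization (0.11, 0.17, 0.16 and 0.35). Autophagy and mitophagy (4 of 17 higher) and immediate early genes (0 of 26 called) passed as lists with adjusted p = 0.0235 and 0.0346, but not with quantile normalization (0.439 and 0.367) or with an estimated correlation (0.417 and 0.914). In all, the autophagy list did not pass in 7 and the immediate early list in 12 of 20 other settings.

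Cell cycle genes lay below other genes in Yanglingquan (median -0.65, adjusted p = 0.00164, 0.738 with an estimated correlation), with 1 of 19 called. This was Cdc20, which starts the exit from mitosis, at -1.26 ± 0.16 (adjusted p = 2.65e-05); the mitotic kinase gene Aurkb stood at -1.47 ± 0.55 and the thymidylate synthase gene Tyms at -0.49 ± 0.20 (adjusted p = 0.0891 and 0.118). The largest decreases were Ntrk2 at -3.19 ± 0.20, from 1.08 to -2.10, and Nnat, an imprinted gene of neurons, at -2.98 ± 0.39, whose other probe stood at -0.85 (adjusted p = 1.62e-09 and 4.97e-05). Mybph, a myosin binding protein gene, was at least 2.94-fold lower. The alpha adrenoceptor gene Adra1d stood at -1.29 ± 0.36 (adjusted p = 0.0245), a call that ended without IRI replicate 4 (adjusted p = 0.0821). In all 1563 genes were called, 527 higher and 1036 lower, and 637 of the lower ones belonged to the faintest of 4 brightness classes of genes, whose median was -0.37 against 0.11 in the brightest. Quantile normalization called 853 (363 higher, 490 lower), normexp 665, the authors' processed values 858 and median scaling 909 higher and 777 lower. The stricter filter called 913, 424 higher and 489 lower.

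**Figure D3:**
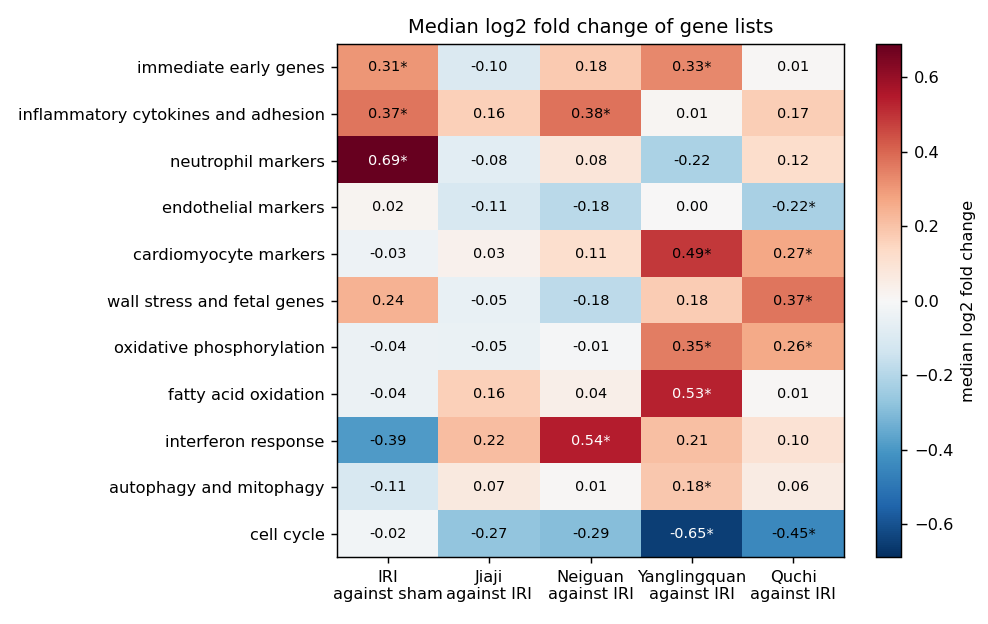
Median log2 fold change (colour and number) of the gene lists that passed camera with the preset correlation in at least 1 of 5 comparisons; stars mark those that passed. Neutrophil markers stand at 0.69 in IRI against sham and fatty acid oxidation at 0.53 in Yanglingquan against IRI. With quantile normalization, oxidative phosphorylation and cardiomyocyte markers lay below other genes in Yanglingquan.

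In Quchi a few genes of stretched heart muscle were called higher and a few endothelial genes lower, with lists that passed with the preset correlation only. Of wall stress and fetal genes, 2 of 13 were called higher (median 0.37, camera adjusted p = 0.00242, 0.64 with an estimated correlation): Csrp3, a stretch sensor of the sarcomere, at 0.64 ± 0.15 and Tnfrsf12a, a receptor of the tumour necrosis factor family, at 0.86 ± 0.21 (adjusted p = 0.018 and 0.0284). Csrp3 was not called with quantile normalization (0.34, adjusted p = 0.0958), nor Tnfrsf12a with normexp (0.65, adjusted p = 0.101), and each call ended in 7 of 23 other settings. Nppa, Nppb and Ankrd1 of the same kind stood at 1.11 ± 0.63, 0.52 ± 0.24 and 0.53 ± 0.24 without passing (adjusted p = 0.233 to 0.357). Of endothelial markers, 2 of 13 were called lower (median -0.22, adjusted p = 0.00457, 0.64 with an estimated correlation), namely the angiopoietin pathway receptor gene Tie1 at -0.77 ± 0.19 and the apelin receptor gene Aplnr at -0.78 ± 0.21 (adjusted p = 0.024 and 0.0417). Both calls ended without IRI replicate 4 (adjusted p = 0.104 and 0.164). In all, the Tie1 call ended in 4 and the Aplnr call in 8 of 23 other settings. Nox4, an oxidase gene that makes hydrogen peroxide, fell by 1.30 ± 0.24 (adjusted p = 0.00403), and Prcp, a peptidase gene of the angiotensin and kinin systems, by 1.34 ± 0.33 (adjusted p = 0.029, and 0.118 without IRI replicate 4). The Prcp call ended in 6 of 23 other settings. The liver-made fibrinogen gene Fgb was at least 4.57-fold higher in Quchi, with 0 of 4 IRI arrays well above background.

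Cell cycle genes lay lower in Quchi (median -0.45, 0 of 19 called, adjusted p = 0.00144, 0.77 with an estimated correlation). Oxidative phosphorylation lay higher (median 0.26, 2 of 34 called, 9 over the list alone, adjusted p = 5.69e-08) and so did cardiomyocyte markers (median 0.27, 0 of 18 called, 5 when adjusted over the list alone, adjusted p = 0.00242), each with 0.64 for an estimated correlation. Random lists of equal brightness had medians of 0.24 and 0.25, and neither list passed with quantile normalization (adjusted p = 0.896 for both). The wall stress list did not pass with quantile normalization (adjusted p = 0.129) or without Quchi replicate 1 (0.0654). Of all genes, 444 were called, 308 higher and 136 lower, and the count rested on single arrays: 122 without Quchi replicate 2, 697 without Quchi replicate 1, 174, 684, 284 and 241 without IRI replicates 1 to 4, and 32 in a fit of these 2 groups alone. Quantile normalization gave 336 higher and 310 lower, median scaling 305 and 220, normexp 298 and 234, and the authors' processed values 340 and 316.

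**Figure D4:**
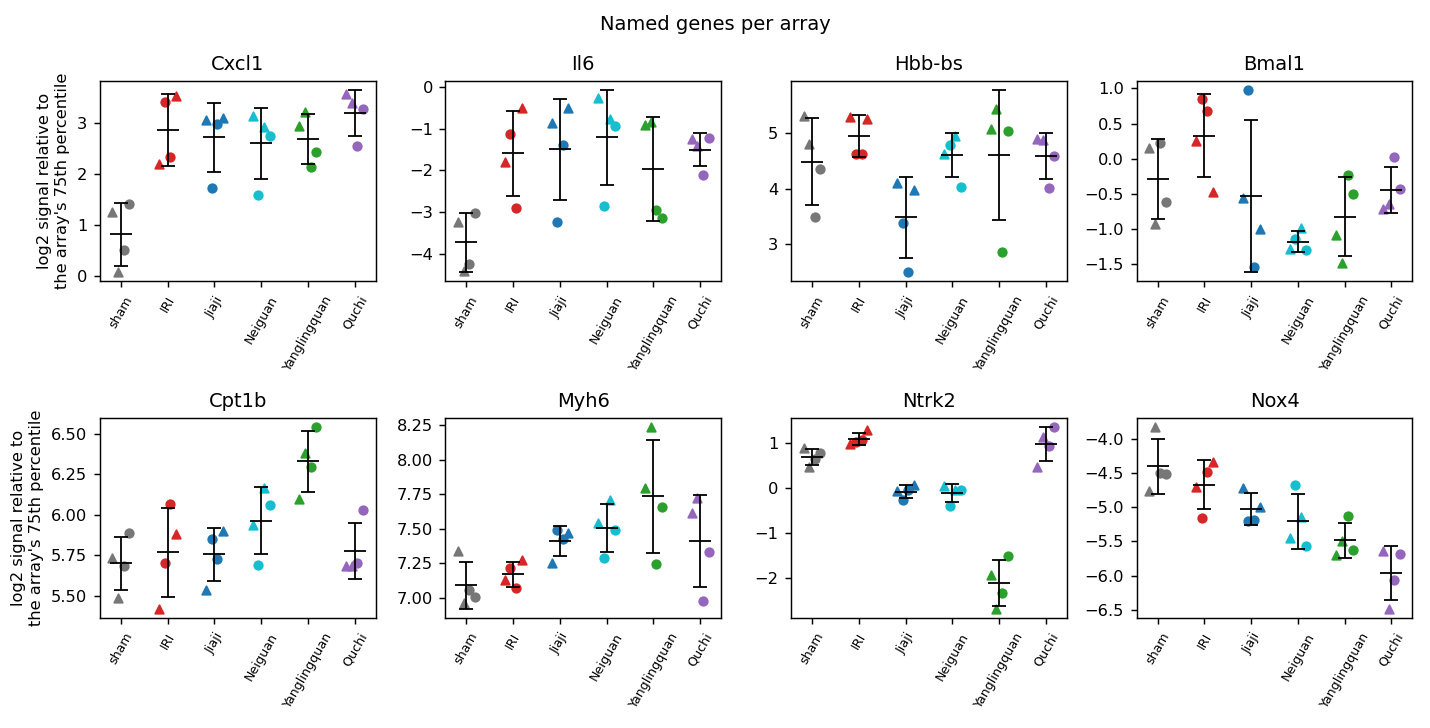
Log2 signal relative to each array's 75th percentile (vertical axes) of 8 named genes per array and group; circles are females, triangles males, bars the mean ± SD of 4 arrays. Cxcl1 lies above the sham arrays in every injured group, and Ntrk2 is lowest in Yanglingquan (mean -2.10). Myh6 is higher in Yanglingquan than in IRI with these values but not with quantile normalization (-0.13).

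A set of 87 genes was called higher than IRI in each of the 4 acupoint groups and 1 gene lower. All 4 comparisons share the same IRI arrays, and the overlap was not tested. The keratin gene Krt80 was higher by 6.34 ± 0.26 in Jiaji, 6.44 ± 0.26 in Neiguan, 6.20 ± 0.26 in Yanglingquan and 5.77 ± 0.26 in Quchi (adjusted p = 1.28e-11 at most). Mcc, a colorectal tumour suppressor gene, ranged from 5.05 to 5.64, the ciliary gene Evc2 from 4.94 to 5.41, the beta defensin gene Defb43 from 4.24 to 4.75, and Pinx1, a telomerase inhibitor gene, from 3.97 to 4.51. Cyp4a2, a fatty acid hydroxylase gene, was at least 7.26-fold to 16.5-fold higher. Of the 87 genes, 38 were also called higher than sham in all 4 groups. Between IRI and sham, 32 of the 87 had been called lower in IRI and 4 higher, against 133 lower of all 12894 genes. That comparison uses the same IRI arrays, so low IRI values by chance alone would favour such an overlap. Fold changes against IRI correlated across genes at r = 0.79 between Jiaji and Neiguan and at 0.30 to 0.46 for the other pairs. Unchanged groups sharing the IRI arrays gave 0.50 in simulation, and splitting the IRI arrays gave 0.58 and 0.16 to 0.28. The covariance exceeded the simulated 0.0298 by 0.134 for Jiaji and Neiguan and by 0.0388 to 0.0583 for the others. Genes are not independent replicates, and scan day parted all acupoint arrays from sham and IRI.

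The acupoint groups differed from each other. By the F test 5035 of 12894 genes differed, led by the histamine receptor gene Hrh3 and by Ntrk2 (adjusted p = 1.41e-07 for both). Hrh3 averaged 2.76 in Jiaji, 2.91 in Neiguan, 2.07 in Yanglingquan and 1.24 in Quchi, and Ntrk2 -0.08, -0.11, -2.10 and 0.98. Against IRI the chosen Hrh3 probe stood at 0.98, 1.13, 0.29 and -0.54 in Jiaji, Neiguan, Yanglingquan and Quchi, and another Hrh3 probe at 0.27, -0.07, -0.86 and 0.02. Cer1, an antagonist of Nodal and BMP signals, averaged -5.13 in Yanglingquan and -3.59 to -2.77 in the others (adjusted p = 3.57e-07). Against IRI, another Cer1 probe stood at -0.01 in Yanglingquan, where the chosen probe stood at -2.38. Each acupoint lay on slides of its own, so these differences include any difference between slides.

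Whether pretreatment brought injured hearts toward sham was measured by the reversal score. On its genes, held-out IRI arrays differed from sham by 0.65 in the signed direction. The same sham arrays had helped to choose the genes, so this value is biased upward as a size of the injury. The score was -0.28 for Yanglingquan, with 4 of 4 arrays below 0 (exact permutation p = 0.0286, adjusted p = 0.114), and -0.11 for Quchi, with 4 of 4 arrays below 0 (exact permutation p = 0.243, adjusted 0.486). It was 0.04 for Jiaji and 0.05 for Neiguan, each with 1 of 4 arrays below 0 (exact permutation p = 0.8286 and 0.786, adjusted 0.8286 for both). None passed after adjustment, but the smallest p the test can give is 0.0143, so a single acupoint could not have passed once adjusted over 4, and this result does not rule a reversal in or out. Of the 610 genes called higher in IRI than in sham, 209 lay in the faintest of 4 brightness classes. The median of that class in Yanglingquan against IRI was -0.37. Whether this shift of faint genes adds to the Yanglingquan score was not tested. Of the injury genes, Il6 differed from IRI by -0.37 to 0.38 in the acupoint groups (adjusted p = 0.71 to 0.952), and Cxcl1, chosen here after its values were seen, by -0.26 to 0.33 (adjusted p = 0.672 to 0.872). Against sham, 3096 genes were called in Jiaji (2252 higher, 844 lower), 2566 in Neiguan (1613 and 953), 1680 in Yanglingquan (749 and 931) and 2720 in Quchi (1526 and 1194). Every acupoint array was scanned on another day than sham, whereas IRI shared the day of sham. These counts therefore include any difference between days and slides. Set beside the 743 of IRI against sham, they do not measure a distance from sham. With quantile normalization the higher and lower counts were 1548 and 2187, 1443 and 2023, 665 and 670, and 1190 and 1723. Normexp gave 1536 and 1222, 1343 and 1236, 554 and 560, and 1201 and 1555; median scaling gave 1640 and 5224, 1382 and 2947, 784 and 753, and 1148 and 1666. The authors' processed values gave 1532 and 2198 for Jiaji, 1444 and 2029 for Neiguan and 1181 and 1731 for Quchi. Single arrays moved the counts of Neiguan (1657 without sham replicate 3, 1676 without Neiguan replicate 1), Yanglingquan (837 without sham replicate 2, 1106 without Yanglingquan replicate 4) and Quchi (1563 without Quchi replicate 2).

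Between the sexes 27 genes were called over all groups, 6 higher and 21 lower in females. Eif2s3 was higher in females by 0.72 ± 0.05, and Sqor, an enzyme of hydrogen sulfide oxidation, by 0.44 ± 0.07 (adjusted p = 5.56e-08 and 0.0109). Mup5, a urinary protein gene of males, stood at -1.68 ± 0.25, the adiponectin family gene C1qtnf6 at -0.98 ± 0.13 and the calcium pump gene Atp2b2 at -1.14 ± 0.16 in females minus males (adjusted p = 0.00474, 0.00134 and 0.00335). These genes were chosen after their values were seen. With quantile normalization 12 genes were higher and 23 lower, and with the authors' processed values 14 and 23. Leaving out 1 array in turn gave 21 to 73 genes. An effect of injury that differed by sex was called for 0 genes by limma, with 632 at an unadjusted p below 0.05 and a smallest adjusted p of 0.173, on 2 arrays per group and sex; without sham replicate 1 the count was 70.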

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

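The tests of the scan day, brightness, cell share, other probes, background, receptor, clock and liver explanations were chosen or reworded only after the results were seen, and only the splits of the arrays were set beforehand. The background and receptor tests replaced earlier ones, on values of 35.1% and 3.46, which did not address the direction of the calls.

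Single arrays stood apart in 6 of 161 groups of 4 values tested with Dixon's test over 6 array measures and the fixed panel, where chance alone would give 8.05. Quchi replicate 1, the only array scanned on the last day, had 595 outlier spots against 292 to 330 on the other Quchi arrays. On principal component 3, IRI replicate 2 scored 21.3 against 5.43 to 6.57, and Neiguan replicate 2 scored -11.8 against -6.89 to -6.09. The myosin gene Myh7 stood at 7.57 in Yanglingquan replicate 4 against 7.23 to 7.27, Pdk4, which restrains glucose oxidation, at 1.78 in IRI replicate 3 against 0.21 to 0.35, and Cpt1b at 6.03 in Quchi replicate 4 against 5.68 to 5.70. The acupoint groups differed from each other for 5035 genes by the F test. Probes left without a gene name, outside the main tests, also held calls: 1184 of 9929 in IRI against sham, and 1469, 942, 1827 and 546 against IRI in Jiaji, Neiguan, Yanglingquan and Quchi.

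Each count of called genes was set beside all 35 splits of the same 8 arrays into 4 and 4. For IRI against sham, and for Jiaji, Neiguan and Yanglingquan against IRI, only the real split (1 of 35) reached its count; the highest other counts were 24, 2, 1 and 1. For Quchi against IRI 2 of 35 splits reached 444, since IRI replicate 2 with Quchi replicates 1 to 3 gave 819 against the rest, so a chance split was not excluded there. Against sham the real split was alone (1 of 35) in each acupoint group, with the highest others at 83, 1, 9 and 609. Among the acupoint groups 1 of 100 draws reached 5035 genes, with 690 as the highest other. For the sexes 2 of 100 draws within groups reached 27 genes, and the other drawn split called 436, which may point to a structure among the arrays that sex does not describe. The numbers of passing lists in IRI against sham, Neiguan, Yanglingquan and Quchi (3, 2, 6 and 5) were reached by 32, 34, 22 and 27 of 35 splits, with 15, 13, 13 and 14 as the highest others, so a chance split was not excluded for any of these. In Jiaji 0 lists passed, which all 35 splits reach by definition, so nothing was tested there.

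A first pattern was a set of 30 genes, Krt80 and Mcc among them, at least 2-fold higher in each acupoint group than in both sham and IRI, with 1 gene the other way. A change of RNA after acupuncture would raise the other probes of these genes, but only 3 of the 30 had any, with a median difference of -0.0208 where the chosen probes of the same genes stood at 2.32, too few to tell. Scan day or array lot could also part the arrays in this way: the last-day Quchi array lay above every sham and IRI array for 96.7% of the genes, which cannot separate a treatment from a lot shared by the later days. Neither explanation was excluded, and another assay of these genes would be needed to choose between them.

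A second pattern was the rise of heart muscle and energy lists in Yanglingquan, the group with the lowest share of probes above background. A scaling that depends on brightness may account for oxidative phosphorylation, at the 18.8 percentile of brightness-matched random lists, and for cardiomyocyte markers, at 89.8. It does not account for the whole shift of fatty acid oxidation, at 100. A higher share of heart muscle cells was left open. All 5 other cell type lists were lower in Yanglingquan, the nearest to 0 being endothelial markers at -0.0387 ± 0.12 (SE). Only fibroblast and matrix genes, at -0.26 ± 0.13, differed by more than their SE. Lymphocyte markers, the lowest, stood at -0.30 ± 0.42. These values are too imprecise to show a fall of the other cell types, so the test could not tell.

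Another pattern was that most calls between IRI and sham were higher in IRI. The tables argue against noise near background as the whole cause: the dimmest of 4 brightness classes of genes held 35.1% of the calls, but in the brightest class 85.1% of the calls were higher (63 of 74, 95% binomial interval 74.96 to 92.3). Receptor genes of smell, pheromones and taste were called 3.46 times as often as other genes of the same brightness (95% interval 2.93 to 4.00), and their median of 0.39 was 0.12 with normexp. Nor was this excess particular to IRI against sham. In Jiaji, Neiguan, Yanglingquan and Quchi against IRI, these receptor genes were called 2.47, 2.21, 1.35 and 1.81 times as often. They were not the whole cause either, since 81.6% of the calls were higher without them (500 of 613, interval 78.3 to 84.6), though all 3 intervals treat genes as independent and are too narrow for genes on the same arrays. The injury itself and a difference between the slides of the 2 groups stayed open and untested.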

How the results depend on the processing

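The alternatives without receptor genes, without the genes called in all 4 acupoint groups and with brightness-matched lists were chosen only after the results were seen. Under alternatives other than leaving out an array, named genes and lists gave 4386 values. Of these, 4057 kept their side of the threshold without turning, 257 lost the call, 41 gained it and 31 turned. Those kept include genes not called in either setting, and F test values have no direction. Leaving out an array gave 2552 values, of which 2317 stayed, 227 lost the call, 8 gained it and 0 turned. Turned means only that the sign changed: a gene not called in either setting counted where its fold change in the main values was at least its SE, however close to 0 the other value lay, and none of the genes or lists that turned passed its threshold on the other side. Signal over background limits the faint genes: with the stricter filter Yanglingquan against IRI held 913 calls in place of 1563. Except where the filter, a fold threshold, the probes tested or fewer arrays made the difference by construction, the cause was not tested.

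With quantile normalization Yanglingquan against IRI had 853 calls, and its lists numbered 2, those of Quchi 2 and those of Neiguan 4. In Yanglingquan the lists of cardiomyocyte markers (adjusted p = 0.56) and oxidative phosphorylation (0.487) turned, as did Tpi1 (-0.13), Gapdh (-0.18), Ankrd1 (-0.0478) and Myh6 (-0.13); Myh6 turned in Jiaji (-0.0465) and Quchi (-0.0862), and Myh7 in Neiguan (-0.038). The authors' processed values gave 858 calls for Yanglingquan, 2, 2 and 4 lists for Yanglingquan, Quchi and Neiguan, and turned the same lists (0.599 and 0.531), Tpi1 (-0.13), Gapdh (-0.17), Ankrd1 (-0.0481), Myh6 (-0.13 in Yanglingquan, -0.0466 in Jiaji, -0.0864 in Quchi) and Myh7 in Neiguan (-0.038). Normexp gave 665 calls for Yanglingquan against IRI, 1114 against sham, 45 for sex, and 2, 2 and 5 lists. It turned cardiomyocyte markers in Yanglingquan (0.518) and Quchi (0.755), oxidative phosphorylation in Yanglingquan (0.667), Tpi1 (-0.16), Gapdh (-0.20), Ankrd1 (-0.0486), Myh6 (-0.13 in Yanglingquan, -0.00438 in Jiaji, -0.10 in Quchi) and Myh7 (-0.0205 in Jiaji, -0.0149 in Neiguan, -0.0322 in Quchi). Median scaling gave 2371 calls in Jiaji against IRI, 6864 against sham, 4329 in Neiguan against sham and 4 lists in Neiguan.

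Every probe tested gave 2168 calls for IRI against sham, 3068, 1865, 3762 and 1167 for Jiaji, Neiguan, Yanglingquan and Quchi against IRI, 7081, 6039, 4349 and 6436 against sham, 10870 among acupoints and 43 for sex. The 2-fold threshold gave 235, then 464, 269, 518 and 172, then 1093, 760, 486 and 650, and 11 for sex. Array weights gave 1380 for IRI against sham, 1999, 1405 and 1632 for Jiaji, Neiguan and Quchi against IRI, 4668 and 4403 for Jiaji and Neiguan against sham, 180 for sex, and 5, 2 and 4 lists in IRI against sham, Jiaji and Neiguan; Nppb in Jiaji turned to 0.15. Only the compared groups gave 32 for Quchi against IRI, 788 and 1789 for Yanglingquan and Quchi against sham and 2 lists in Jiaji. The stricter filter gave 48 and the trended robust prior 49 genes for sex, and no filter gave 29 genes for injury by sex. With an estimated correlation 0 lists passed in any comparison. Without the genes called in all 4 groups Quchi had 292 calls.

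Scan as a random block had a negative consensus correlation (-0.0998), which narrows the errors, so its higher counts were not read as more changes: 1637 for IRI against sham, 2527, 1806, 3042 and 1324 against IRI, 4942, 4622, 3407 and 4293 against sham, and 7565 among acupoints. The replicate number was not taken as a pairing. Same-numbered arrays of different groups had mean correlations of -0.02, -0.01, 0.07 and 0.09, and 24 of 60 such pairs were over 0.1. With different numbers and groups the mean was -0.01 and 46 of 180 pairs were over 0.1. For arrays of the same sex in different groups 45 of 120 were. Closest to their own number were 9 of 24 arrays. Replicate 1 was male in every group, so number and sex overlap, and these values do not settle whether a pairing existed. As a block the replicate number gave 714 calls for IRI against sham, 1298, 736, 1526 and 398 against IRI, 3058, 2635, 1629 and 2708 against sham, 5047 among acupoints, 3 for sex and 0 for injury by sex, with 3, 0, 2, 7 and 5 lists. Since number and sex overlap, the block can take up part of the difference between the sexes.

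The reversal score turned in Jiaji with 100 genes (-0.0748), quantile normalization (-0.0393), median scaling (-0.0648) and the authors' processed values (-0.0347), in Neiguan with 100 genes (-0.0122) and median scaling (-0.0119), and in Quchi with 2000 genes (0.014). The mean correlation between acupoint groups moved from 0.46 to 0.29 with the IRI arrays split.

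Leaving out single arrays gave 440 to 663 calls for IRI against sham, 861 to 1248 for Jiaji against IRI, 456 to 673 for Neiguan, 1072 to 1360 for Yanglingquan and 122 to 697 for Quchi. Against sham the ranges were 2271 to 3098, 1657 to 2737, 837 to 1596 and 1563 to 2924, among acupoints 3904 to 5476, for sex 21 to 73 and for injury by sex 0 to 70. The high counts for sex came without sham replicate 4 (73), Jiaji replicates 1 (57) and 2 (43), and Neiguan replicates 2 (51) and 3 (46). Lists ranged from 3 to 6, 0 to 1, 2 to 6, 5 to 10 and 3 to 6. They numbered 6 in IRI against sham without IRI replicate 1 or sham replicate 2 and 5 without IRI replicate 2. In Neiguan they numbered 6 without IRI replicate 2 or Neiguan replicate 2, and 4 without IRI replicate 1 or Neiguan replicate 3. Yanglingquan had 10 without its replicate 4, and Quchi 3 without its replicate 1. Jiaji had 1 without IRI replicate 1 or 4 or Jiaji replicate 1 or 4. Reversal scores ranged from 0.01 to 0.11 in Jiaji, 0.03 to 0.09 in Neiguan, -0.32 to -0.21 in Yanglingquan and -0.14 to -0.03 in Quchi. Camera was not run with the random scan block, the sex term was not dropped from the sex comparisons, and the 2-fold threshold was not applied to the F test, which has no single fold change.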

Other observations

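The tests of the clock arms, of liver transcripts, of their left-out arrays and of each acupoint against the others were chosen only after the results were seen, as were the genes named here.

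Single clock genes were called in some acupoint groups, while the circadian clock list passed in none (adjusted p = 0.395 to 0.843). Per3 was higher than IRI by 0.96 ± 0.15 in Jiaji and 0.55 ± 0.15 in Yanglingquan (limma adjusted p = 0.000215 and 0.0205), with its other 2 probes at 0.08 and 0.29 on average and the Yanglingquan call lost in 6 of 23 other settings, and Bmal1 was lower by 1.15 ± 0.37 in Yanglingquan (log2 fold change -1.15, adjusted p = 0.0487). A different clock phase at collection could part evening genes from morning genes. The difference of the 2 arms was 1.14 in IRI, 1.90 in Neiguan and 1.92 in Yanglingquan, but the smallest adjusted exact p over 5 comparisons was 0.143, and no unadjusted p could fall under 0.0286 with 4 arrays per group, so the test could not tell. Slc7a11, the cystine importer, was higher in IRI than in sham by 0.54 ± 0.14 and lower in Yanglingquan than in IRI by 0.57 ± 0.14 (adjusted p = 0.0213 and 0.0093), and the call in Yanglingquan ended in 4 of 23 other settings, with quantile normalization among them (-0.40, adjusted p = 0.0717). Both Slc7a11 differences use the same IRI arrays, so high IRI values by chance alone would favour such a pair. The collagen genes Col1a1 and Col3a1 stood lower in females than in males by 0.96 ± 0.16 and 0.67 ± 0.12 (adjusted p = 0.0109 for both). Per3 in Jiaji, Bmal1 in Yanglingquan, Slc7a11 in IRI and the collagen genes were not run under other settings.

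Liver transcripts were seen on some acupoint arrays. Alb was higher in Neiguan than in IRI by 4.07 ± 1.17 (adjusted p = 0.0436). This rested largely on Neiguan replicate 1 at 1.47, with the other Neiguan arrays at -4.69 to -3.07 and the IRI arrays at -8.27 to -4.48, and without that array the call ended (2.91 ± 1.104, adjusted p = 0.19), as it did without IRI replicate 2 or 4 or Neiguan replicate 3 or 4 (adjusted p = 0.0511 to 0.137). Serpina1 was higher in Jiaji by 1.30 ± 0.29 (adjusted p = 0.00622, and at most 0.0325 without any single array). In Jiaji 5 of the 10 measured liver transcripts stood above IRI, 3 of them called. Alb in Jiaji, at -7.91 to -6.48, lay within the range of the IRI arrays. RNA of liver in the heart samples might raise such transcripts together: their median over 10 measured genes was 0.53 in Quchi and 0.51 in Neiguan, between the bounds set for the test, which could not tell. Neiguan replicate 1 had the highest liver score, -1.73, where the other arrays lay between -4.26 and -2.54. Quchi replicates 1 and 2 came next at -2.63 and -2.54, with Alb at -0.86 and -1.85 and Fgb at -3.14 and -3.92. Of the 10 genes 9 stood above IRI in Quchi, but not every member rose on these 2 arrays. Ahsg stood at -5.50 and -5.10 there, against -5.50 to -4.87 in IRI. Apoh stood at -7.79 and -6.83, against -8.90 to -5.88 in IRI. In Quchi replicates 3 and 4 Alb stood at -3.66 and -7.98 and Fgb at -5.42 and -5.63.

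Each acupoint was also compared with the arrays of the other 3 pooled as a group, all scanned on the later days. Yanglingquan differed in 2547 genes (614 higher, 1933 lower), Quchi in 1359 (755 and 604), Jiaji in 103 (86 and 17) and Neiguan in 0. Differences among the pooled 3 acupoints added to the error of each comparison, by an amount that depends on which acupoints were pooled. These counts therefore do not rank the acupoints, and the 0 does not show that Neiguan was like the others.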
